A study of Homo sapiens with 3 samples.

How the data were processed

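Transcript abundance was measured by RNA sequencing in HCT116, an established human colon cancer cell line. Total RNA was taken from 3 cultures: cells left untreated, cells exposed to 1 µM palbociclib for 24 hours, and cells transfected for 24 hours with a small interfering RNA (siRNA) against CDK4. Palbociclib is an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6, and an siRNA lowers the amount of its target mRNA. There was 1 library per group. Table columns were matched to the libraries by the library titles. No library from cells given a non-targeting siRNA, transfection reagent alone or drug solvent was analysed here, so the untreated library was the only control.

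A table of read counts per gene and a table of FPKM values per gene were deposited. Per the submitters' processing notes, HTSeq 0.6.1, DESeq and the hg19 genome build were used. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. Whether reads of a gene were counted apart from those of its antisense or overlapping neighbour is therefore not known. The deposited counts are whole numbers and are not normalised. The deposited FPKM values are the authors' rescaling of the same counts by gene length and library total. This was checked over 16938 genes with reads in every library, where the largest relative deviation was 9e-12, so FPKM adds no independent measurement. FPKM served only as an alternative unit.

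Both tables hold 48162 entries in the same order, with gene symbols but no gene identifiers or coordinates. There were 47971 distinct symbols. Where a symbol occurs more than once, a named gene was taken from the entry with the most reads. Another 29 entries carry a spreadsheet date in place of a symbol. They held 0.196% of the untreated, 0.201% of the siRNA and 0.148% of the palbociclib reads, stayed in the totals and are not named. The library totals were 20313597 reads for untreated, 18349355 for CDK4 siRNA and 18020870 for palbociclib.

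Counts were normalised with TMM factors from edgeR 4.0.16 in R 4.3.3. The factors were 1.03 for untreated, 1.07 for CDK4 siRNA and 0.901 for palbociclib. Normalised levels are given as CPM, computed on the scaled library totals. Log2 ratios were taken after adding a prior count of 2, while ratios printed without a log are ratios of CPM with no prior count. Each ratio has an exact 95% interval from the Clopper-Pearson interval of the share of reads that falls in the numerator library. Each CPM has an exact Poisson interval. Sequencing reads without molecular identifiers are not independent molecules, so all intervals, and the floor of 3 counts used for genes without reads, cover counting error only. That floor corresponds to 0.143 CPM in the untreated, 0.152 in the siRNA and 0.185 in the palbociclib library.

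With 1 library per group there is no estimate of the spread between cultures. No p-value was computed, and every difference is a difference between libraries with no replicate check. Genes were compared when their mean CPM over the 3 libraries was at least 1, which left 12694 genes. A gene was counted as higher or lower by a size rule: a log2 ratio of at least 1 in either direction, and a counting interval that excludes 1. The comparisons were each treated library against the untreated one, and palbociclib against siRNA directly. The treated-against-untreated comparisons share the untreated library. Therefore 3 unchanged libraries, 1 of them a shared control, were simulated 100 times. Noise was Poisson, alone or with added biological coefficients of variation (BCV) of 0.1 or 0.2. Gene means were pooled over the 3 real libraries, palbociclib included. A gene high only with palbociclib thus had too many simulated untreated and siRNA reads, and a gene low only there too few.

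The choices made before the data were examined were the comparisons, the size rule, 30 gene lists, the rule for named genes and most alternative settings. The lists cover cell cycle, DNA repair, death receptor genes, stress responses, metabolism, immune genes, differentiation, signalling and markers of blood, fibroblast and endothelial cells. For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A list is said to stand apart below the 0.5th or above the 99.5th percentile. This describes these libraries and is no test of the conditions. Of the 30 lists, 27 had enough members, and lists of independently varying genes would put 0.27 of them apart per comparison. Members of a list can vary together and some lists share members, so more could stand apart without an effect of a treatment. The genes named are 14 fixed genes, the 8 highest and 8 lowest genes of each comparison at a mean CPM of at least 5 with an interval on 1 side of 1, up to 4 leading members and the furthest contrary member of each list that stands apart, the 6 genes furthest past the size rule in both treated libraries, and genes past it in opposite directions. Other members of the fixed lists, and a few genes so marked in the text, were named after their values were seen. Of the ranked genes, some were left out of the text, among them pseudogenes and clone-named transcripts. A few of these genes and 1 gene list are not reported here.

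The procedure was tested on simulated counts with gene means pooled over the libraries and the scaled library totals, with 200 genes altered. For the siRNA comparison with Poisson noise, run on 12671 genes, the rule found 98.5% of genes with a true 4-fold difference, 40.3% of those at 2-fold and 0% of those at 1.5-fold, and called 0.0802% of unaltered genes. For the palbociclib comparison, run on 12694 genes, the shares were 97%, 46.3% and 4.48%, with 0.096% of unaltered genes called. With a BCV of 0.1 the intervals covered 1 for 57.9% of the unaltered genes of the siRNA comparison and 59.8% of those of the palbociclib comparison. At such a spread the intervals would be too narrow; the spread of these cultures was not measured. The list procedure was run with a BCV of 0.1 on 12678 genes. Of 100 simulated lists of 20 unaltered genes none stood apart, and of 100 lists shifted by a log2 ratio of 0.5 all 100 did. Their members were drawn at random and varied independently, so lists whose members vary together were not tested.

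Alternative settings were DESeq2 1.42.0 median-of-ratios size factors, total counts alone, no low-count filter or a minimum mean CPM of 5, prior counts of 0.5 and 10, deposited FPKM with pseudocounts of 1 and 0.1, a 1.5-fold size rule, a 99% interval, and lists without members shared with another list. After the data were seen, a correction for GC content and gene length, a restriction to protein-coding genes and 4 further gene lists were added. Gene types and GC content came from the GENCODE annotation of GRCh38, matched by symbol or RefSeq synonym. Of the compared genes, 94.9% could be matched, and no coordinates of that build are used. Lengths were recovered from the ratio of counts to FPKM. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.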

Results

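The data are the gene-level read counts of 3 HCT116 RNA-seq libraries: 1 from untreated cells, 1 from cells 24 hours after transfection with an siRNA against CDK4, and 1 from cells after 24 hours in 1 µM palbociclib. HCT116 is a human colon cancer line. The libraries held 20313597, 18349355 and 18020870 reads, in which 20012, 21218 and 20422 genes had at least 1 read. The design asks how the loss of CDK4 mRNA and chemical inhibition of CDK4 and CDK6 differ from the untreated state, with interest in p73 (gene TP73) and in death receptor 5 (gene TNFRSF10B). There are no replicates, so each value comes from 1 library per group. Brackets hold 95% intervals for counting error only.

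The siRNA target was lower in the library of transfected cells. CDK4 had 2689 reads in the untreated, 1059 in the siRNA and 1426 in the palbociclib library, which correspond to 128 CPM (123 to 133), 53.8 CPM (50.6 to 57.1) and 87.8 CPM (83.3 to 92.5). The siRNA library thus held 0.42 of the untreated CDK4 level (0.391 to 0.451), and the palbociclib library 0.686 (0.643 to 0.732). The related kinase gene CDK6 was at 0.779 of the untreated level with siRNA (0.732 to 0.83) and at 1.69 with palbociclib (1.61 to 1.79).

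The genes of the study's question differed in level between the treated libraries. TNFRSF10B, which encodes a receptor for the death ligand TRAIL, was higher in both treated libraries: 1.79 times the untreated level with siRNA (1.67 to 1.92), below the 2-fold rule, and 3.38 times with palbociclib (3.17 to 3.61). TNFRSF10A, the gene of the other signalling TRAIL receptor, was at 1.07 (0.97 to 1.18) with siRNA and at 2.89 (2.66 to 3.15) with palbociclib. TP73 mRNA was at 1.15 (1.06 to 1.24) with siRNA and at 0.447 (0.398 to 0.502) with palbociclib. CDKN1A, which encodes the CDK inhibitor p21, was lower with siRNA at 0.704 (0.68 to 0.729) and higher with palbociclib at 1.65 (1.61 to 1.7). CD274, the gene of the checkpoint ligand PD-L1, was close to the detection limit, with 21, 26 and 8 reads, and its intervals against the untreated library included 1.

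**Figure D1:**
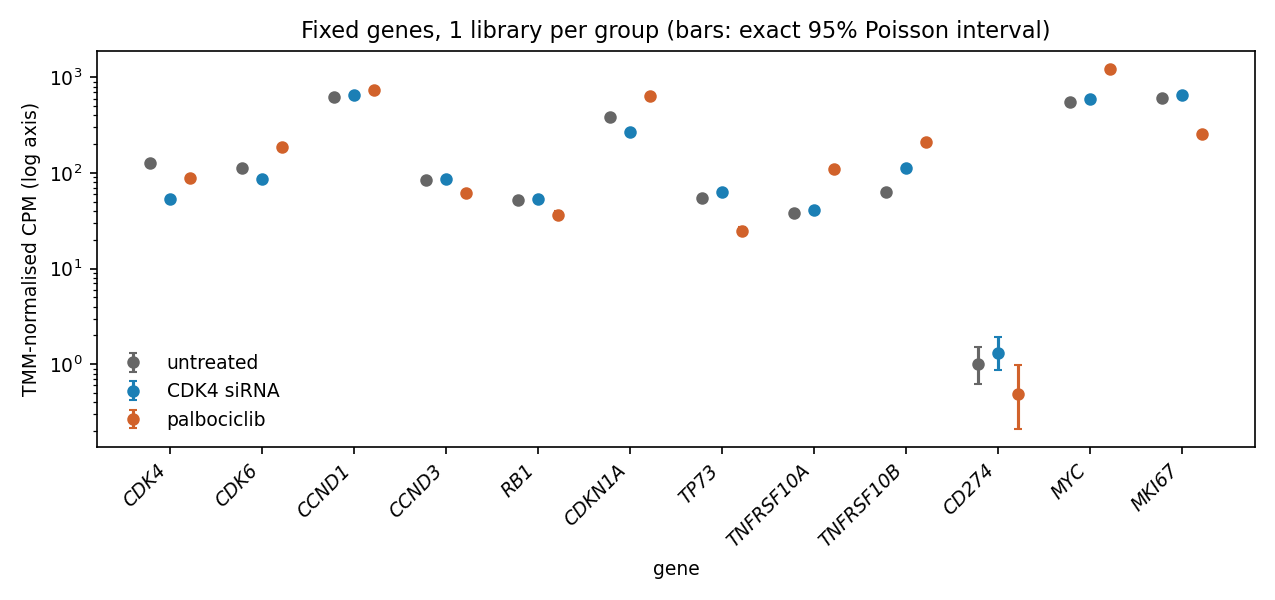
TMM-normalised CPM on a log axis (vertical) of 12 of the fixed genes (horizontal) in the untreated, CDK4 siRNA and palbociclib libraries, 1 point per library, with exact 95% Poisson intervals that cover counting error only. CDK4 is lowest in the siRNA library at 53.8 CPM, TNFRSF10B is highest in the palbociclib library at 212 CPM, and CCND2, without reads in any library, is left out.

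CDK4 siRNA against untreated. Few genes passed the size rule: 140 were higher and 15 lower of 12694, or 1.22%. The 8 highest by the naming rule include TNXB, which encodes the matrix protein tenascin-X, at 3.73 times the untreated level (2.43 to 5.9), TRIM66 at 3.21 (2.43 to 4.3), PABPC1L at 2.91 (2.2 to 3.88), MAPK15 at 2.89 (2.09 to 4.05) and the cadherin gene CELSR3 at 2.79 (2.21 to 3.54). They also include the nuclear long non-coding RNA NEAT1 at 2.82 (2.49 to 3.19) and the transcription factor gene FOXE3 at 4.48 (1.64 to 15.2), the latter from 5 against 21 reads. Among genes with a mean CPM of at least 5, the lowest was CDK4 itself, the only 1 of them past the size rule as lower. It was followed by the histone genes HIST1H2BD at 0.505 (0.33 to 0.76) and HIST1H2BK at 0.532 (0.442 to 0.637), by SMAD7, an inhibitor of TGF-beta signalling, at 0.515 (0.383 to 0.687), and by the keratin gene KRT6A at 0.576 (0.434 to 0.759). Reads of histone genes can be split between near-identical copies, so their values are uncertain.

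Cell cycle genes in the siRNA library lay near the untreated level. None of the 30 genes of G1/S transition, the 36 of DNA replication or the 38 of mitosis passed the size rule, and the median log2 ratios of −0.04, −0.05 and −0.06 lay inside the range of random lists. The proliferation marker MKI67 was at 1.07 (1.04 to 1.1), the cyclin gene CCND1 at 1.04 (1.02 to 1.07), CCND3 at 1.03 (0.963 to 1.1) and RB1 at 1.02 (0.94 to 1.11). CCND2 had no reads in any library, which allows up to 0.176, 0.187 and 0.227 CPM by the exact intervals. In the same library, MYC was at 1.08 (1.05 to 1.11).

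In the siRNA library 3 of 27 lists stood apart, all towards lower levels by small amounts and with no member past the size rule. The list of cholesterol synthesis genes had a median log2 ratio of −0.19, with 14 of 22 intervals below 1. Its leading members were INSIG1, a feedback regulator of sterol synthesis, at 0.639 (0.586 to 0.696), and the enzyme genes FDFT1 at 0.78 (0.738 to 0.823) and NSDHL at 0.799 (0.718 to 0.889). Hypoxia and glycolysis genes had a median of −0.20, with 13 of 19 intervals below 1, including ALDOC at 0.642 (0.536 to 0.768), BNIP3L at 0.709 (0.619 to 0.812) and PFKFB4 at 0.717 (0.616 to 0.834). Cytosolic ribosomal protein genes had a median of −0.19, with 29 of 30 intervals below 1. RPL37 was at 0.825 (0.794 to 0.857) and RPL19 at 0.833 (0.815 to 0.852). The ribosomal protein list no longer stood apart once trends with GC content and length were subtracted, where its median was −0.12. Log2 ratios of this comparison followed GC content across genes, with a Spearman correlation of 0.328, against 0.0579 for palbociclib.

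How many genes pass the size rule in the absence of an effect depends on the unknown spread between cultures. Simulated unchanged libraries gave 4.14 higher and 4.59 lower genes with Poisson noise, 10.3 and 10.8 with a BCV of 0.1, and 150 and 151 with a BCV of 0.2. Their gene means were pooled over all libraries, so counting noise at genes with few reads can differ from the real comparison. The simulated robust standard deviations of the log2 ratios were 0.0832, 0.24 and 0.432, against 0.219 observed. Both added BCVs thus gave a wider spread than the one seen, and a BCV of 0.2 at every gene gave 10 times as many lower genes as the 15 seen. Higher genes were 90.3% of the observed calls. The simulated noise was the same in both directions, so no setting could have given such an excess. The simulations therefore do not bear on its source. The count was 33 at a mean CPM of at least 5 and 436 without a low-count filter, so most of these genes had few reads.

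Palbociclib against untreated. In the palbociclib library 1269 genes were higher and 1722 lower by the size rule, 23.6% of those compared. The robust standard deviation of the log2 ratios was 0.81, against 0.22 for the siRNA comparison. Of the 27 lists, 13 stood apart, 7 towards higher and 6 towards lower levels. Total-count scaling in place of TMM took the median of all genes from −0.07 to −0.27. The share of higher genes among the calls was then 25.7% in place of 42.4%, and it was 27.3% and 25.8% with the deposited FPKM. Directions of single genes with ratios close to 1 are to be read relative to that shift. Every list that stood apart for palbociclib kept its sign under these scalings.

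Genes of the cell cycle were lower in the palbociclib library. Of 38 mitotic genes 29 were lower by the size rule and none higher, with a median log2 ratio of −1.29. KIF20A, a mitotic kinesin, was at 0.139 (0.123 to 0.157), the kinase genes NEK2 at 0.225 (0.193 to 0.26) and AURKA at 0.227 (0.206 to 0.248), and MKI67 at 0.419 (0.405 to 0.434). Among G1/S and E2F target genes 15 of 30 were lower, with a median of −1.0. They include RRM2, a subunit of ribonucleotide reductase, at 0.183 (0.173 to 0.193) and cyclin gene CCNE2 at 0.187 (0.125 to 0.272), while UNG went the other way at 1.45 (1.37 to 1.55). DNA replication genes had 16 of 36 members lower and a median of −0.98, led by the polymerase subunit genes POLA2 at 0.182 (0.146 to 0.224) and POLE2 at 0.207 (0.157 to 0.269). The contrary members were ORC6 at 1.39 (1.25 to 1.54) for replication and CKS1B at 1.35 (1.28 to 1.42) for mitosis. The symbol CKS1B has 2 entries, of which the entry with the most reads was used. Genes of homologous recombination and Fanconi repair had 9 of 17 members lower and a median of −1.21, among them RAD51AP1 at 0.279 (0.227 to 0.342), BRIP1 at 0.299 (0.252 to 0.353) and BRCA1 at 0.341 (0.299 to 0.388).

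The cyclins, CDKs and CDK inhibitors did not stand apart as a list, with 3 members higher and 5 lower of 22. CDKN2C, which encodes the CDK4 and CDK6 inhibitor p18, was among the lowest of all genes at 0.0837 (0.0549 to 0.123). CDKN1C, named after its values were seen like CDKN2B, was at 7.5 (6.9 to 8.15), and CDKN2B, the gene of p15, at 3.63 (3.07 to 4.31). RB1 was at 0.702 (0.634 to 0.777), CCND3 at 0.72 (0.665 to 0.778), CCND1 at 1.18 (1.15 to 1.2) and MYC at 2.22 (2.16 to 2.27). With total-count scaling MYC was below the 2-fold rule, at a log2 ratio of 0.95.

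The lists of cholesterol synthesis, ATF4 and immediate early genes stood apart towards higher levels in the palbociclib library. Of 22 cholesterol synthesis genes 18 were higher and none lower, with all 22 intervals above 1 and a median log2 ratio of 1.99. INSIG1 was at 11.2 (10.6 to 11.8), MSMO1 at 8.67 (8.09 to 9.3) and HMGCS1 at 8.24 (7.75 to 8.76). Genes of the ATF4 branch of the stress response had 13 of 19 members higher, 1 lower and a median of 1.52. ATF3 was at 18.3 (16.6 to 20.3), PPP1R15A at 8.88 (8.28 to 9.53) and the cystine transporter gene SLC7A11 at 7.65 (7.07 to 8.28), whereas ATF5 was at 0.318 (0.263 to 0.382). Immediate early and MAPK target genes had 13 of 20 members higher and a median of 1.43. The AP-1 genes FOS at 21.3 (18.4 to 24.7), JUN at 18.9 (17.6 to 20.3) and FOSB at 11.8 (9.93 to 14.1) led them, and ETV4 went the other way at 0.561 (0.502 to 0.626).

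NF-kB targets and cytokines had 9 of 13 measured members higher and a median log2 ratio of 1.71. The chemokine gene IL8 was at 31.7 (24.1 to 42.5), the apoptosis inhibitor gene BIRC3 at 10.2 (8.32 to 12.7) and RELB, an NF-kB subunit, at 9.27 (8.46 to 10.2). Interferon-stimulated genes were lower, with 10 of 24 members past the rule and a median of −0.94. IFI35 was at 0.237 (0.169 to 0.326), IFIT1 at 0.238 (0.135 to 0.395) and USP18 at 0.254 (0.18 to 0.351). Without a low-count filter this list had a median of −0.41 and did not stand apart. The epithelial-mesenchymal and TGF-beta list had 6 members higher and 2 lower of 11, with a median of 1.25. CTGF was at 43.8 (29.5 to 68.1) and CYR61 at 13.1 (11.6 to 14.9), while fibronectin gene FN1 was at 0.428 (0.329 to 0.551). CTGF and CYR61 are also known as growth factor and AP-1 responsive genes.

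Genes of mitochondria and ribosomes went in different directions. All 13 mitochondrially encoded mRNAs had intervals above 1, with 6 past the size rule and a median log2 ratio of 0.96. MT-CYB was at 2.59 (2.56 to 2.62) and MT-ATP8 at 3.27 (2.82 to 3.81), and with total-count scaling these 2 alone were past the rule. Of 30 cytosolic ribosomal protein genes all had intervals above 1 and 1, RPL30, passed the rule at 2.08 (1.97 to 2.19), which it did not with total-count scaling, at a log2 ratio of 0.86. Their median was 0.51. Nuclear genes of oxidative phosphorylation had a median of −0.50, with 21 of 22 intervals below 1 and 3 members past the rule, namely NDUFB3 at 0.243 (0.204 to 0.289), UQCRC2 at 0.452 (0.421 to 0.486) and NDUFS3 at 0.495 (0.449 to 0.544). That list stood inside the random range when GC content and length trends were subtracted, at −0.32. Composition also differed. Mitochondrially encoded mRNAs made up 6.53% of the palbociclib reads against 4.02% of the untreated and 3.85% of the siRNA reads. Ribosomal protein genes made up 7.53% against 6.11% and 5.66%, the 28S ribosomal RNA gene had 7759 reads against 2085 and 2549, and the nuclear RNA MALAT1 had 13502 against 1355 and 2211.

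The BCL2 family did not stand apart for palbociclib, at a median log2 ratio of 0.00 with 4 members higher and 1 lower of 14. The higher members include PMAIP1, the gene of the BH3-only protein NOXA, at 7.55 (6.91 to 8.25), and BBC3, the gene of PUMA, at 3.52 (3.28 to 3.79). The death receptor list had a median of 0.08, with 5 members higher and none lower of 18. These were TNFRSF10A, TNFRSF10B, the decoy receptor gene TNFRSF10D at 5.6 (5.24 to 6), BIRC2 at 2.01 (1.84 to 2.2), which was below the rule with total-count scaling, and BIRC3. The initiator caspase gene CASP8 was at 0.672 (0.597 to 0.756) and the adaptor gene FADD at 0.581 (0.479 to 0.703). These members were named after their values were seen. Medians of antigen presentation at −0.19, checkpoint and NK ligands at 0.37, the unfolded protein response at 0.59, heat shock at −0.08 and lysosome and autophagy at 0.42 lay inside the random range. So did those of ribosome biogenesis at −0.05, hypoxia and glycolysis at −0.09, intestinal differentiation at −0.00, Wnt targets at 0.15 and histones at 0.88.

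The furthest single genes were not all members of the lists. METTL7B was at 0.0654 (0.0344 to 0.114), the retinoid enzyme gene DHRS3 at 0.0737 (0.0582 to 0.0921), LZTS1 at 0.0786 (0.0412 to 0.137), and the spindle genes PSRC1 at 0.0983 (0.0777 to 0.123) and SPC24 at 0.103 (0.0764 to 0.136). At the other end were the small nucleolar RNA gene SNORD3A at 86.8 (50.5 to 164), FOXE3 at 68.8 (29.1 to 214), the stress gene GADD45G at 39.8 (19.9 to 93.2), RASD1 at 31.2 (18 to 59.3) and ARC at 29.7 (27.8 to 31.8). SNORD3A belongs to a family of near-identical copies, so its reads are uncertain. The non-coding RNAs RPPH1, MALAT1 and 28S rRNA were also higher in the palbociclib library. Whether library preparation or RNA quality differed between the libraries was not examined. ARC had 20688 reads with palbociclib against 901 in the untreated and 841 in the siRNA library.

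**Figure D2:**
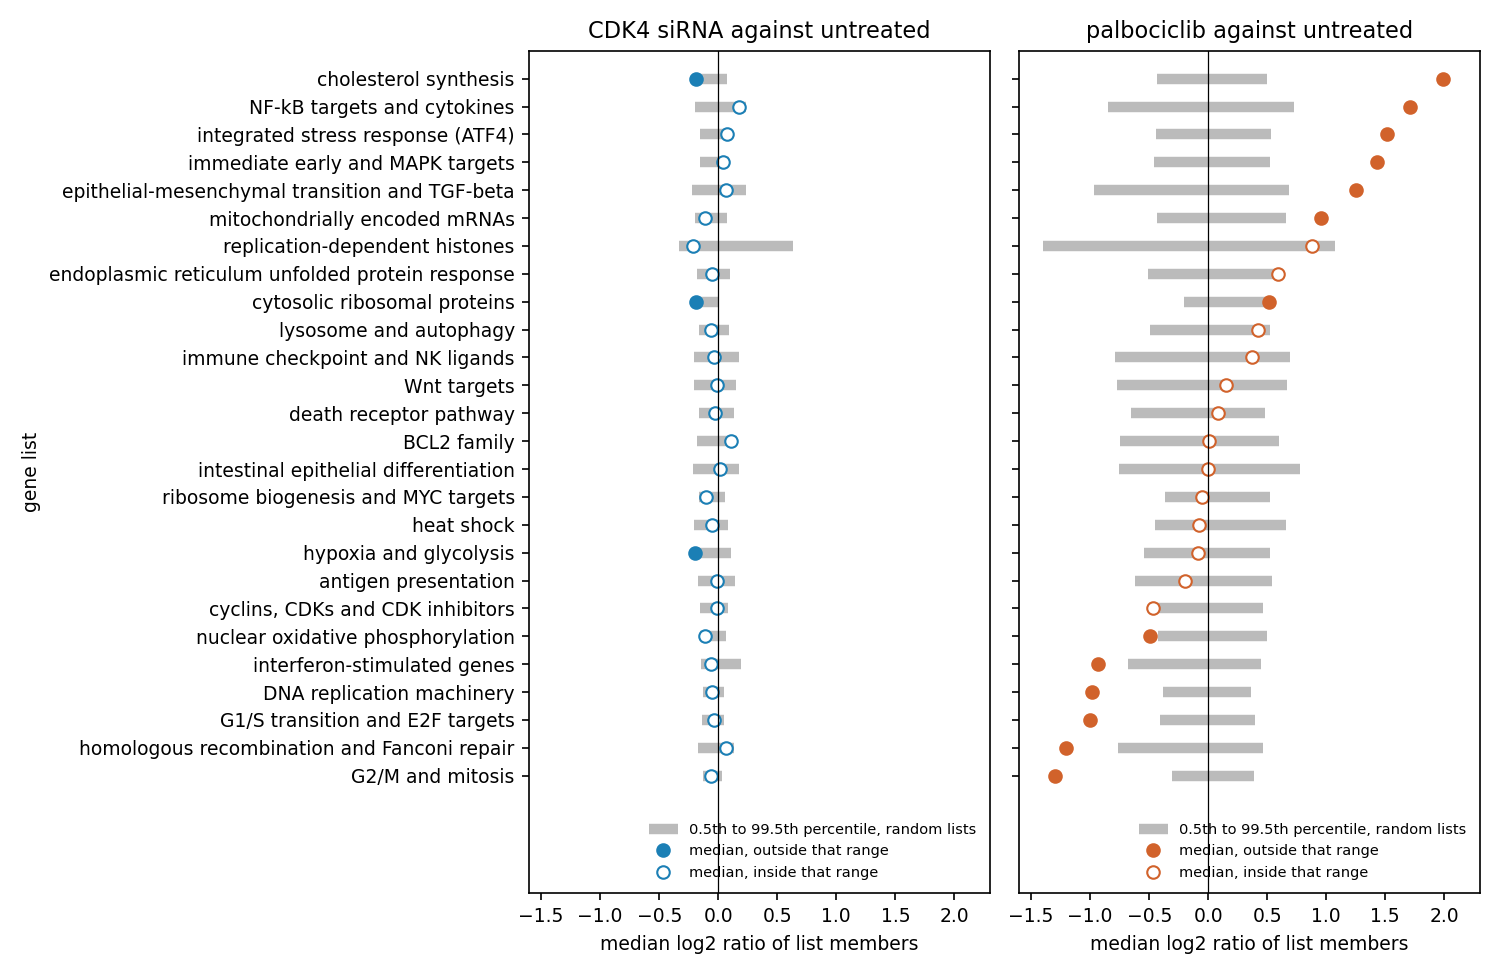
Median log2 ratio of the measured members of each of 26 fixed gene lists (horizontal axis) for CDK4 siRNA and for palbociclib, each against the untreated library; grey bars span the range of all but the outermost 1% of 10000 random lists matched on expression, and filled points lie outside them. The palbociclib medians run from −1.29 for mitosis to 1.99 for cholesterol synthesis, while the siRNA medians stay within −0.22 and 0.18.

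Both treatments. Genes higher in both treated libraries numbered 79, or 56.4% of those higher with siRNA, where independent lists of these sizes would share 14.0. Simulated unchanged libraries that share a simulated control gave 1.1, 2.46 and 34.5 such genes with Poisson noise and BCVs of 0.1 and 0.2. The real untreated control is 1 library and cannot be divided, so its share in the overlap was not measured. The simulations also left palbociclib unchanged, whereas 1269 genes were higher with it here. They therefore do not give the overlap, higher or lower, that a shared control alone would produce in these data. The genes furthest past the rule in both were TNXB, FOXE3, CELSR3, MAPK15, EXD3 and FSTL3. EXD3 was at 2.49 (1.88 to 3.34) with siRNA and 5.5 (4.24 to 7.23) with palbociclib. FSTL3, which encodes an activin-binding protein, was at 2.34 (2.08 to 2.63) and 3.29 (2.93 to 3.69). Lower in both were 4 genes, against 2.03 for independent lists and 0.13, 0.6 and 14.4 for simulated unchanged libraries with a shared control. Of these STS, ILDR2 and TMEM249, named after their values were seen, had between 9 and 50 reads per library, and the remaining gene is a clone-named transcript.

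Across the 12694 genes the log2 ratios of both comparisons had a Pearson correlation of 0.247, with a bootstrap interval over genes of 0.226 to 0.269, and a Spearman correlation of 0.212. Genes are not independent replicates. Unchanged libraries with a shared control gave correlations of 0.459, 0.483 and 0.495 at the 3 noise levels. Those libraries lacked the wide spread of the palbociclib ratios, so their correlations are not directly comparable with 0.247. The covariance was 0.0689, against 0.0118, 0.0324 and 0.0955 in the simulations, so the difference was 0.0572 and 0.0366 at the lower noise levels and −0.0265 at a BCV of 0.2.

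**Figure D3:**
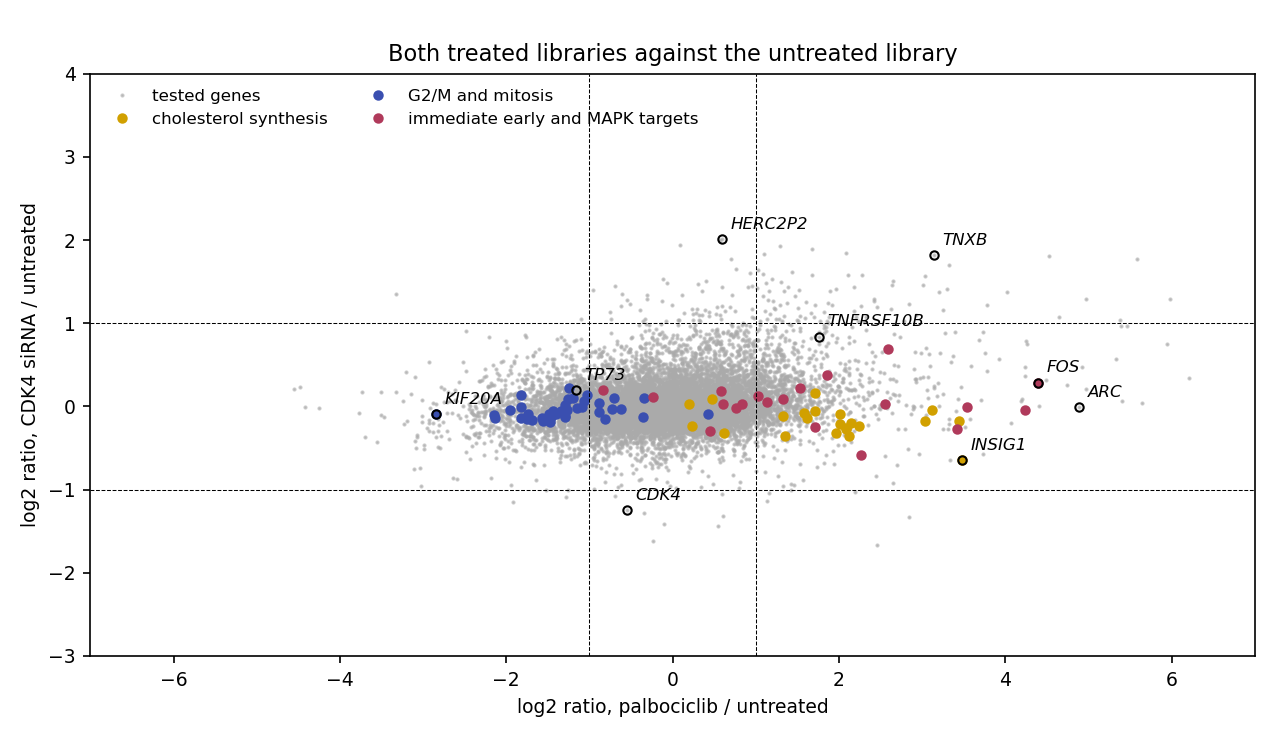
Log2 ratio of each of the 12694 compared genes against the untreated library with palbociclib (horizontal axis) and with CDK4 siRNA (vertical axis); dashed lines mark a 2-fold difference, and colours mark 3 gene lists. Cholesterol synthesis genes and mitotic genes spread along the palbociclib axis, whereas CDK4 is below the lower siRNA line at 0.42 of the untreated level.

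Palbociclib against CDK4 siRNA. Compared directly, 1111 genes were higher and 1753 lower with palbociclib, 22.6% of those compared. Total-count scaling gave a share of higher genes of 19.8% in place of 38.8%, with the median of all genes at −0.33 in place of −0.08, and the deposited FPKM gave 23.8% and 21.1%. TNFRSF10B was at 1.89 times the siRNA level (1.79 to 1.99), TNFRSF10A at 2.7 (2.48 to 2.94), CDKN1A at 2.35 (2.27 to 2.43), CDK6 at 2.17 (2.05 to 2.31), CDK4 at 1.63 (1.51 to 1.77), TP73 at 0.39 (0.348 to 0.437) and MKI67 at 0.392 (0.379 to 0.406). The 14 lists that stood apart were the 13 of the comparison with untreated cells and the replication-dependent histones. Of 7 measured histone genes 5 were higher and none lower, with a median log2 ratio of 1.21. HIST1H2BD was at 5.56 (3.86 to 8.21) and HIST1H1C at 2.46 (1.93 to 3.17). That list did not stand apart without a low-count filter. The nuclear oxidative phosphorylation list, at −0.36, lost its place outside the random range under 6 of the alternatives. The lowest genes were DHRS3 at 0.0653 (0.0516 to 0.0816), METTL7B at 0.0692 (0.0363 to 0.121) and CDKN2C at 0.0739 (0.0485 to 0.108). Among the highest were ARC at 29.8 (27.9 to 32), CTGF at 28.5 (20.5 to 41) and PMEPA1, a TGF-beta responsive gene, at 23.5 (14.4 to 40.8).

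Most markers of other cell types were low. Of 12 blood, 10 fibroblast and 7 endothelial markers found in the tables, 1 of each list reached a mean of 1 CPM. CD14 had 0, 3 and 52 reads in the untreated, siRNA and palbociclib libraries, and CD79A, below that mean, had 4, 4 and 38. COL1A1 had 310, 434 and 141 reads while COL1A2 had none, ESAM had 188, 168 and 68 reads, and the leukocyte gene PTPRC had none in any library.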

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

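The GC content and length correction used in this part was chosen only after the results were seen, as were the breadth of the palbociclib differences and the genes higher with siRNA as patterns to weigh. The other results were picked by a rule fixed before the values were seen, which picks a fixed list that stands apart in both treated libraries with opposite signs, or a gene past the size rule in opposite directions. Each rests on 1 library per group, and the difference was not tested.

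Cholesterol synthesis genes had a median log2 ratio of −0.19 with siRNA and 1.99 with palbociclib, each outside the random range. A bias with GC content and gene length was a question mainly for the small siRNA median. Log2 ratios had a Spearman correlation with GC content of 0.328 for siRNA and only 0.0579 for palbociclib. After those trends were subtracted the siRNA median was −0.16 and the palbociclib median 2.10, and both stayed outside the range. The test does not separate an effect of the siRNA or the drug from differences between cultures, such as density or medium.

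Ribosomal protein genes had a median log2 ratio of −0.19 with siRNA and 0.51 with palbociclib, but after GC content and length trends were subtracted the siRNA median was −0.12 and inside the random range.

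MSH5 had 20, 51 and 0 reads in the untreated, siRNA and palbociclib libraries, a log2 ratio of 1.35 with siRNA and a level 5.15-fold lower with palbociclib when a floor of 3 reads is set against the untreated level. The exact interval of that ratio reaches up to 0.262. RPPH1, the RNA component of RNase P, had log2 ratios of −1.66 and 2.46 from 25, 6 and 114 reads. SLC10A5 had −1.13 and 1.13 from 26, 10 and 46 reads. MXRA8 had 1.05 and −1.10 from 22, 45 and 7 reads. Independent lists of these sizes would hold 19.0 genes higher with siRNA and lower with palbociclib, where 2 were found, and 1.5 of the other kind, where 3 were found. The shared untreated library makes opposite calls rarer than that, and unchanged libraries gave at most 0.02 of either kind. In those simulations the palbociclib library was unchanged as well. The value of 0.02 is therefore not the number expected beside a palbociclib library with many differences, and chance is not excluded.

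The breadth of the palbociclib differences was weighed against technical explanations. If GC content and length bias were a likely source, few calls would remain after subtraction, but 2693 remained against 2771 before among genes with known GC content, 2478 of them the same genes. The Spearman correlations with GC content and length were only 0.0579 and 0.0738. Little could thus be subtracted, and the outcome followed from these weak trends. If a scale set by abundant genes were the source, some single scale factor would remove most calls, but the lowest number over all factors was 2965 of 2991. That followed from the wide spread of the ratios, with 1269 calls higher and 1722 lower, so it is no separate evidence. Effects of the drug, of its solvent, of a separate culture and of library preparation are not told apart by these tests.

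The genes higher in the siRNA library were weighed in the same way. After GC content and length trends were subtracted, 109 remained against 119 before, 101 of them the same genes. The log2 ratios of all genes had a robust standard deviation of only 0.219. Average trends within that spread could bring few genes below a log2 ratio of 1, so this count is no separate evidence. More non-coding RNA in the library could be another source, but the 466 genes typed other than protein-coding had a median log2 ratio of 0.0866, with a 95% bootstrap interval over genes of 0.0522 to 0.151. This lay below the bound of 0.25 set for this pattern, which was itself chosen after the results were seen. The interval does not cover the spread between cultures. Non-coding genes were still 17.6% of the typed higher genes against 3.87% of all typed genes, which remains open. Transfection itself was not examined, since no library with a non-targeting siRNA was analysed here.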

How the results depend on the processing

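The GC content and length correction, the restriction to protein-coding genes and the alternative forms of the added lists were chosen only after the results were seen. No paired analysis was possible because each group has 1 library, and leaving a library out would end a comparison. CDK4 and TNFRSF10B kept their direction under every alternative. Counts of genes stayed within 1.5 times the first value with DESeq2 size factors, a prior count of 0.5, a 99% interval and protein-coding genes only. Where values moved, the cause was not tested, except that a filter, a larger prior or pseudocount and a 1.5-fold rule alter by construction how many genes can pass. Depth limits genes with few reads most.

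Genes higher with siRNA, 140, numbered 436 without a filter, 33 at a mean CPM of 5, 71 with a prior of 10, 22 with FPKM and a pseudocount of 1, and 481 with a 1.5-fold rule. Genes lower with siRNA, 15, numbered 103, 1, 5, 4 and 115 under the same settings. Genes higher with palbociclib, 1269, numbered 841 with total counts, 2076 without a filter, 499 and 704 with FPKM and pseudocounts of 1 and 0.1, and 2578 with a 1.5-fold rule. Those lower, 1722, numbered 3216 with a 1.5-fold rule. In the direct comparison the 1111 higher genes numbered 655, 1721, 433, 571 and 2471 in that order of settings, and the 1753 lower genes 2646 with total counts, 1167 at a mean CPM of 5 and 3269 with a 1.5-fold rule. Genes higher in both, 79, numbered 155 without a filter, 19 at a mean CPM of 5, 27 with a prior of 10, 6 and 50 with FPKM, and 223 with a 1.5-fold rule. Genes lower in both, 4, numbered 2 with total counts, 33 without a filter, 0 at a mean CPM of 5, 0 with a prior of 10, 1 with FPKM and a pseudocount of 1, 46 with a 1.5-fold rule and 2 after the GC correction. The correlation of both log2 ratios across genes, 0.247, was 0.299 without a filter, 0.219 at a mean CPM of 5, 0.216 and 0.225 with FPKM, and 0.226 after the GC correction.

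List medians that moved into the random range were histones in the direct comparison without a filter (0.59), interferon-stimulated genes with palbociclib without a filter (−0.41) and in the direct comparison with FPKM and a pseudocount of 1 (−0.66), and ribosomal proteins with siRNA after the GC correction (−0.12). Nuclear oxidative phosphorylation moved in with palbociclib under FPKM with a pseudocount of 1 (−0.65) and the GC correction (−0.32). In the direct comparison it did so under DESeq2 factors (−0.30), total counts (−0.62), no filter (−0.32), FPKM (−0.58 and −0.62) and the GC correction (−0.22). Medians that moved out were ATF4 genes with siRNA without a filter (0.10), with FPKM (0.11 and 0.12), after the GC correction (0.10) and without shared members (0.10), and lysosome and autophagy genes in the direct comparison at a mean CPM of 5 (0.58), with FPKM (0.33 and 0.33) and after the GC correction (0.62). The median of mitochondrially encoded mRNAs with siRNA, −0.11 and inside the range, reversed to 0.066 and moved outside after the GC correction.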

Other observations

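The 4 gene lists of this part, and the removal of members that were named genes, belonged to a fixed list or were noted as seen, were chosen only after the results were seen. Targets of NRF2, a regulator of the antioxidant response, were higher as a list in the palbociclib library. The median log2 ratio of 14 measured members was 0.68, at percentile 99.8 of random lists, and 0.82 with all members as first written. By the size rule 5 were higher and 1 lower, and 8 lay within 2-fold. OSGIN1 was at 10.6 (9.87 to 11.4), the thioredoxin reductase gene TXNRD1 at 5.23 (5.12 to 5.34) and the glutathione synthesis genes GCLC at 4.91 (4.64 to 5.2) and GCLM at 2.86 (2.69 to 3.04). NQO1, also a known target, was at 0.983 (0.952 to 1.01), and ABCC2 at 0.42 (0.374 to 0.471). The hypothesis that members not seen before are higher as well passed its test at 0.68, but 3 members had intervals below 1, and a list chosen after seeing the data is weak evidence.

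The hypotheses for the other 3 lists were left open by their tests. Translation-related mRNAs with a 5' TOP motif other than ribosomal proteins had a median of 0.49 with palbociclib, at percentile 98.8, inside the random range, where all members as first written gave 0.62 and lay outside it. EIF4B was at 2.93 (2.87 to 2.99) and EIF3F at 2.45 (2.35 to 2.55). YAP/TEAD targets had a median of 0.51 with palbociclib, at percentile 98.8 and inside the range, against 0.58 outside it with all members. AMOTL2 was at 6.42 (5.96 to 6.93) and LATS2 at 4.43 (4.06 to 4.84), while 4 of 12 members had intervals below 1, among them FSTL1 at 0.647 (0.518 to 0.804), F3 at 0.736 (0.616 to 0.877) and AXL at 0.766 (0.696 to 0.843). Transcripts known for nuclear or intron retention had a median of 0.145 with siRNA, at percentile 99.2 and inside the range, against 0.37 outside it with all members. This was not particular to siRNA, since with palbociclib the medians were 0.41 inside the range and 0.92 outside it with all members. In these comparisons the 3 lists thus stood apart only with the members that had led to them. In the direct comparison the 5' TOP list stood apart in both forms, at 0.65 and 0.67.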
